A study of Mus musculus with 21 samples.

How the data were processed

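The arrays carry long oligonucleotide probes for mouse transcripts and were hybridized in a single channel. Per the labels, cells were sorted with biotin-conjugated antibodies against Notch1 or Glast and anti-biotin microbeads, RNA was amplified to biotin-labelled cRNA, and the arrays were stained with a streptavidin dye. Per the file headers, images were taken at a pixel size of 5 µm and a detector setting of 650 and read with GenePix Pro 4.1.1.4. The deposited scanner files give spot and background intensity in scanner units, and their flag column marks spots that the software did not find. The deposited processed table is not on a log scale. The authors' values equal spot median minus background median, floored at 1, times a factor per array (0.327 to 2.53), for nearly all bright spots. Among 5372 to 12196 spots compared per array, 0 to 4 deviated by over 1%. The tool behind the authors' values is not given in the sources.

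Scanner intensities were background-corrected with normexp (offset 50) over all spots, limited to 34312 transcript probes, quantile normalized and put on the log2 scale. The other 4568 spots, controls and further probe classes, were not used for tests. A probe was kept if it was found on every array of at least 1 group, which left 25264 probes. Gene symbols came from matching the probes' accessions to a RefSeq table of assembly GRCm38.p6, used for names only. In all 22987 probes had 1 symbol, 0 had several and 11325 had none. The brightest kept probe stood for a gene, giving 12612 genes, of which 4015 had more than 1 kept probe. No probe matched Mki67 by accession, so this gene, fixed beforehand, has no value here.

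The model in limma 3.58.1 (R 4.3.3) had a mean for each of 8 groups and 13 residual degrees of freedom, with empirical Bayes moderation. Genes were called at an adjusted p under 0.05 (Benjamini-Hochberg per comparison). The 12 comparisons, of which 4 were main ones, and the 29 gene lists were fixed before the data were examined. The lists cover Müller glia, glial transport, retinal progenitors, neurogenic factors, the Notch pathway, DNA replication, mitosis, CDK inhibitors, rods, cones, bipolar cells, amacrine and horizontal cells, ganglion cells, microglia, vessels, astrocytes, pigment epithelium, lens, erythroid cells, gliosis, immediate-early and stress genes, interferon and MHC class I, chromatin and DNA methylation, reprogramming and pluripotency, Müller regeneration, sterol synthesis, glycolysis, matrix, and synaptic vesicles. Lists were tested with camera at a preset correlation of 0.01. Counts within a list were also taken with p adjusted over the list alone. Of these lists, CDK inhibitors, amacrine and horizontal cells, and reprogramming and pluripotency were called in no comparison. Tables and figures used data.table (version 1.17.8), jsonlite 2.0.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

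Genes named in the report follow a rule fixed beforehand: 9 genes chosen in advance, the genes with the largest called change whose arrays did not overlap (6 per direction in main comparisons and 3 in others), and in main comparisons the list members with the smallest adjusted p. Some of these genes are not reported here. Among named genes with several probes, probes pointed in opposite directions by over 0.5 on the log2 scale for 1 of 54 (Pkm) between Notch1+ P14 and P0, 5 of 51 (Cdkn2c, Sox2, Hk1, Nrxn3 and Stx3) between Glast+ P28 and P7, 3 of 47 (Ehmt1, Fdps and Fn1) between the sorts at P7 and 0 of 49 at P14. Probes spanned over 2 (log2) for 15, 11, 6 and 14 of these genes. Simulation with 200 changed genes recovered 39% to 62% of 2-fold and 85% to 94% of 4-fold changes in the main comparisons. Of calls 2.94% to 4.4% were false. Real arrays, with shared scan-day deviations, may differ.

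Replicate numbers were checked as pairs: deviations of equal-numbered arrays correlated above 0.1 for all pairs only between Notch1+ P14 and P7 (0.28 to 0.60), so the main model has no pairing and a replicate block was run as an alternative. Alternatives fixed beforehand were median scaling, cyclic loess, the authors' values (with 50 added before the log), no background correction, no filter on dim probes, the mean of a gene's probes, a trended prior, a 2-fold filter, a fit of the compared groups only, a replicate block, scan day as a block, leaving out each array, camera with an estimated correlation and fry. A filter at the 95th percentile of the 94 negative-control probes, a fit within scan day 2 and the averaging of the P28 arrays were chosen after the data had been seen.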

Results

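Gene expression was measured in cells taken from the retinas of C57BL/6 mice between birth and postnatal day 28 (P28), a period in which the last retinal progenitors stop dividing and Müller glia, the main glial cells of the retina, mature. Cells were captured on magnetic beads through a surface protein. Notch1+ cells carry the receptor Notch1, which keeps progenitors undifferentiated, and were taken at P0, P3, P7 and P14 with 3 arrays at each age. Glast+ cells carry the glutamate transporter Slc1a3 (Glast), present on radial and Müller glia, and were taken at P7 (2 arrays), P14 (3 arrays), P21 (2 arrays) and P28 (2 arrays). The submitters class the Notch1+ cells as progenitors and the Glast+ cells as glial precursors and then adult Müller glia. The labels state 2 to 3 independent biological replicates per age, and the p-values rest on the spread between those arrays, pooled over all groups.

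Each of the 21 arrays held 38880 spots, of which 34312 were probes for mouse transcripts analysed here. The scanner software found between 55.4% and 80.1% of these probes on an array. In the Notch1+ arrays 11.4% to 34.1% of probes lay at or below their local background, against 0.297% to 1.51% in the Glast+ arrays. The number of arrays limits the precision. Replicates correlated with r = 0.937 to 0.995 across probes, which are not independent replicates. Replicate 3 of Notch1+ P14 stood apart from the other arrays of its group (r = 0.955 and 0.937). The pair at P28 carries a single sample code (20 codes for 21 arrays) and differed by an SD of 0.143 on the log2 scale, less than any other pair of replicates, so P28 may be 1 sample on 2 arrays. The arrays were kept as 2, as the labels number them, and counts with them averaged to 1 are given beside the P28 comparisons. Those hold no spread from P28. The arrays were scanned on 3 days. Day 1 held 1 Notch1+ array of each age, day 2 the other 8 Notch1+ arrays and day 3 all 9 Glast+ arrays, so that sort and scan day cannot be told apart. Deviations of Notch1+ arrays from their group means had a median correlation across genes of 0.27 between ages on a shared scan day (30 pairs) and −0.37 between days (24 pairs).

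Differences between groups were tested with limma over 12612 genes and called at a Benjamini-Hochberg adjusted p under 0.05. Log2 differences are on the normalized intensity scale. A gene's value is that of its brightest probe, and where the probes of a named gene span over 2 on the log2 scale the value furthest from it is given too. Slc1a3 lay near the top of the scale in most Glast+ arrays, where differences are compressed. Where the probes of a gene were not found, or were saturated, on every array of a group, the ratio is a bound, written as "at least N-fold": the bright group's mean against the dim group's mean of, per array, the lowest signal among found probes or the probe's own if that was higher. Genes with the largest changes were named only if the arrays of both groups did not overlap, which chance gives in 10% of genes for 3 against 3 arrays, 20% for 3 against 2 and 33.3% for 2 against 2. The 29 gene lists were tested with limma's camera at a preset correlation. Of 179 list calls over 12 comparisons, 11 held with an estimated correlation and 148 with fry, which asks whether a list's genes move on balance in a single direction. Groups, tests, lists and naming rule were fixed beforehand.

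**Figure D1:**
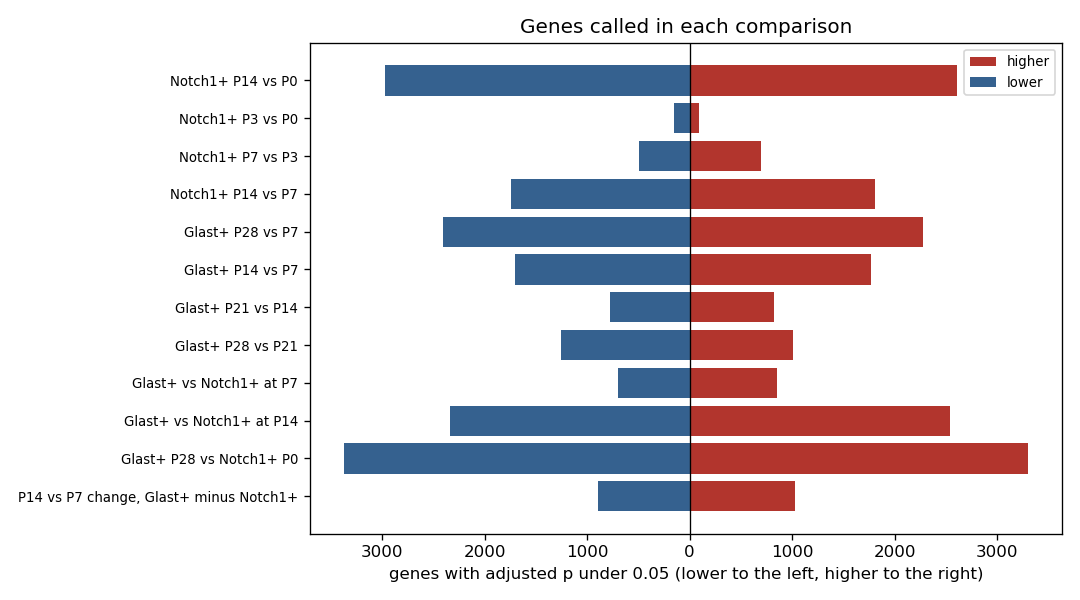
Number of genes called higher and lower in each comparison (x axis, genes; bars start at 0). The comparison of P3 with P0 in Notch1+ cells has the fewest calls (250) and that of Glast+ P28 with Notch1+ P0 the most (6672).

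The comparison of Notch1+ cells at P14 and P0 asks what changes over the whole span of that sort. Genes of dividing and neurogenic progenitors fell, and genes of rods, blood vessels and microglia rose. Of 12612 genes, 5583 were called, 2610 higher and 2973 lower at P14. Notch1 fell by 0.99 on the log2 scale (14.16 ± 0.28 at P14, 15.16 ± 0.13 at P0, SD, n = 3 each, adjusted p = 0.000325). Rlbp1, a retinaldehyde-binding protein of Müller glia, rose by 3.66 (SE 0.48, adjusted p = 8.56e-06) and Glul, the glutamine synthetase of Müller glia, by 1.64 (SE 0.37, adjusted p = 0.00141). Neither Slc1a3 (0.60, SE 0.41, adjusted p = 0.266) nor Gfap (adjusted p = 0.714), whose probe was found on 1 of 6 arrays, passed the test. Slc1a3 was 1.14 higher and called without replicate 2 of P14 and −0.04 without replicate 3.

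The 6 genes with the largest rise were Icam2 (8.59), Aplnr (8.56), Robo4, Mmrn2 (8.21), Vwf (8.18) and Ptprb, all known from endothelial cells, with SE 0.43 to 0.51 and adjusted p = 3.38e-10 to 1.97e-09. Their probes were found on all P14 arrays and on 0 (Robo4, Ptprb) or 1 of 3 P0 arrays. By its probe Ptprb was at least 289-fold higher at P14, but its other probe rose by 4.33. The other probe of Robo4, found at P0, rose by 1.44 only, and no size is given for this gene. Largest among the falls were those of the somatostatin receptor Sstr2 (−7.28), the ganglion-cell factor Atoh7 (−6.23), the ciliary gene Rsph1 (−5.83), Ptf1a (−5.83) and Foxn4 (−5.20), which specify amacrine and horizontal cells, and the progenitor growth factor Fgf15 (−5.73), with SE 0.22 to 0.44 and adjusted p = 2.23e-11 to 1.32e-08. Atoh7 was found on no P14 array and was at least 75.2-fold lower there. Sstr2 and Rsph1 were found on 2 and Ptf1a on 1 of 3 P14 arrays. Ccnd1 (cyclin D1), saturated on all P0 arrays, was at least 1.62-fold lower (adjusted p = 0.032), and the largest fall among its 4 probes was −2.66. This call ended with cyclic loess, with the authors' processed values, within scan day 2, and without replicate 1 or 3 of P0 or replicate 1 or 2 of P14.

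Cell-cycle genes fell together in the Notch1+ cells. Of 33 genes of mitosis and G2/M, 32 were lower at P14 (also 32 adjusted over the list alone), with a median of −2.72, among them the topoisomerase Top2a (−3.57, SE 0.20, adjusted p = 8.16e-10) and the cyclin Ccnb1 (−3.80, SE 0.27, adjusted p = 8.14e-09). Of 29 genes of DNA replication and G1/S, 28 were lower (28 adjusted over the list alone), with a median of −1.85, including the helicase subunit Mcm7 (−2.53). Neurogenic transcription factors fell in 18 of 22 cases (19 adjusted over the list alone, median −2.33). Of 19 progenitor genes, 16 were lower and 2 higher (the same adjusted over the list alone, median −1.62), with the Notch target Hes5 at −4.23 and the intermediate filament gene Nes at 2.43 (0.16 by its other probe). Chromatin and DNA methylation genes were lower in 14 of 28 cases and higher in 1 (16 and 1 adjusted over the list alone, median −0.62), with the maintenance methyltransferase Dnmt1 at −1.98 and the histone methyltransferase Ezh2 at −2.32. For these 5 lists adjusted p = 7.89e-18 to 0.000582, and adjusted p = 0.102 to 0.212 with an estimated correlation. Sterol synthesis genes were lower in 13 of 19 cases and higher in 1 (15 and 1 adjusted over the list alone, median −1.82, adjusted p = 3.19e-05, adjusted p = 0.0243 with an estimated correlation), with the squalene epoxidase Sqle at −2.51.

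Vascular genes were higher in 19 of 21 cases (20 adjusted over the list alone) with a median of 5.05, including the VEGF receptor Flt1 (7.43, SE 0.38, and 2.11 by its other probe) and the endothelial cadherin Cdh5, at least 103-fold higher at P14. Microglial genes were higher in 18 of 20 cases (19 adjusted over the list alone, median 3.44), with Laptm5 at 6.70 and the complement gene C1qa at 4.86. Rod genes rose in 20 of 27 cases (21 adjusted over the list alone, median 2.89), among them the phosphodiesterase subunits Pde6b (5.18) and Pde6g (4.62). Interferon and MHC class I genes were higher in 16 of 19 cases (16 adjusted over the list alone, median 2.46), with the immunoproteasome subunit Psmb8 at 5.98 (0.36 by another probe). Matrix and basement membrane genes were higher in 13 of 23 cases and lower in 2 (the same adjusted over the list alone, median 1.70), with the nidogen Nid2 at 6.74. Glycolysis genes were higher in 12 of 19 cases and lower in 1 (the same adjusted over the list alone, median 0.84), including Aldoa (2.54). For these 6 lists adjusted p = 1.03e-15 to 0.000274, and adjusted p = 0.102 to 0.212 with an estimated correlation.

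Of 23 Müller glia genes, 10 were higher and 1 lower at P14 (the same adjusted over the list alone, median 0.63), with the clusterin gene Clu at 5.35, Apoe at 2.67 and Timp3, a metalloproteinase inhibitor, at 3.68 (0.54 by its other probe). The call (adjusted p = 0.000348, and adjusted p = 0.34 with an estimated correlation) ended without replicate 3 of P14 (median 0.16), the array with the highest mean of this list in its group (0.50, against −0.31 and −1.05) and the lowest mean of the vascular list (2.45, against 3.64 and 3.27). Glial transport (median 0.68), reactive gliosis (0.63), immediate-early and stress (0.89), erythroid (1.22), astrocyte (0.77) and bipolar genes (0.65) rose too. For these 6 lists adjusted p = 0.000462 to 0.043, and adjusted p = 0.107 to 0.566 with an estimated correlation. The bipolar call ended without replicate 1 of P0 (0.65, adjusted p = 0.0578), without replicate 3 of P14 (0.57) and with scan day as a block (0.65, adjusted p = 0.0565), and the astrocyte call without replicate 3 of P14 (0.24) and with the block (0.77, adjusted p = 0.0505).

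The other 10 lists were not called between P0 and P14. Their medians were 0.29 for lens genes (adjusted p = 0.0686, though adjusted p = 4.7e-06 with fry), 0.77 for cone genes (adjusted p = 0.139), 0.27 for reprogramming and pluripotency genes (adjusted p = 0.186, though adjusted p = 0.00499 with fry) and 0.25 for synaptic vesicle genes (adjusted p = 0.227). They were −0.67 for amacrine and horizontal cell genes (adjusted p = 0.325), 0.03 for ganglion cell genes (adjusted p = 0.625), −0.17 for the Notch pathway (adjusted p = 0.679) and 0.01 for pigment epithelium genes (adjusted p = 0.679). The Notch pathway split, with 7 of 24 members higher and 11 lower (8 and 11 adjusted over the list alone). The ligand Jag1 (4.49) rose and the ligand Dll1 (−3.34) fell. Whether vascular cells gave the rises was not tested. Of 7 CDK inhibitors, 2 were higher, including Cdkn2b (3.41), and 2 lower, including Cdkn2c (−1.65), in the whole set and adjusted over the list alone, with a median of −0.24, a mean of 0.46 and an upward test (adjusted p = 0.882). The 18 Müller regeneration factors had a median of 0.04, a mean of −0.24 and an upward test (adjusted p = 0.996).

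With scan day as a block 6122 genes were called between P14 and P0. Each age has 1 array on day 1 and 2 on day 2, so the block changes the spread and cannot move a difference. Within day 2 (2 arrays per age) 4685 genes were called, and all 19 called lists had the same sign there and on day 1 (1 array per age, no test). For day 2 and day 1 the medians were −2.87 and −2.44 for mitosis, −2.11 and −1.39 for replication, −2.02 and −3.39 for neurogenic factors, −1.08 and −2.41 for progenitor genes, and −1.84 and −1.34 for sterol synthesis. They were 5.19 and 5.15 for vascular, 4.1 and 2.55 for microglial, 3.33 and 2.22 for rod, 1.97 and 2.88 for interferon and 1.02 and 0.05 for Müller glia genes. Cyclic loess turned the balance of calls, to 3324 higher and 2351 lower.

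**Figure D2:**
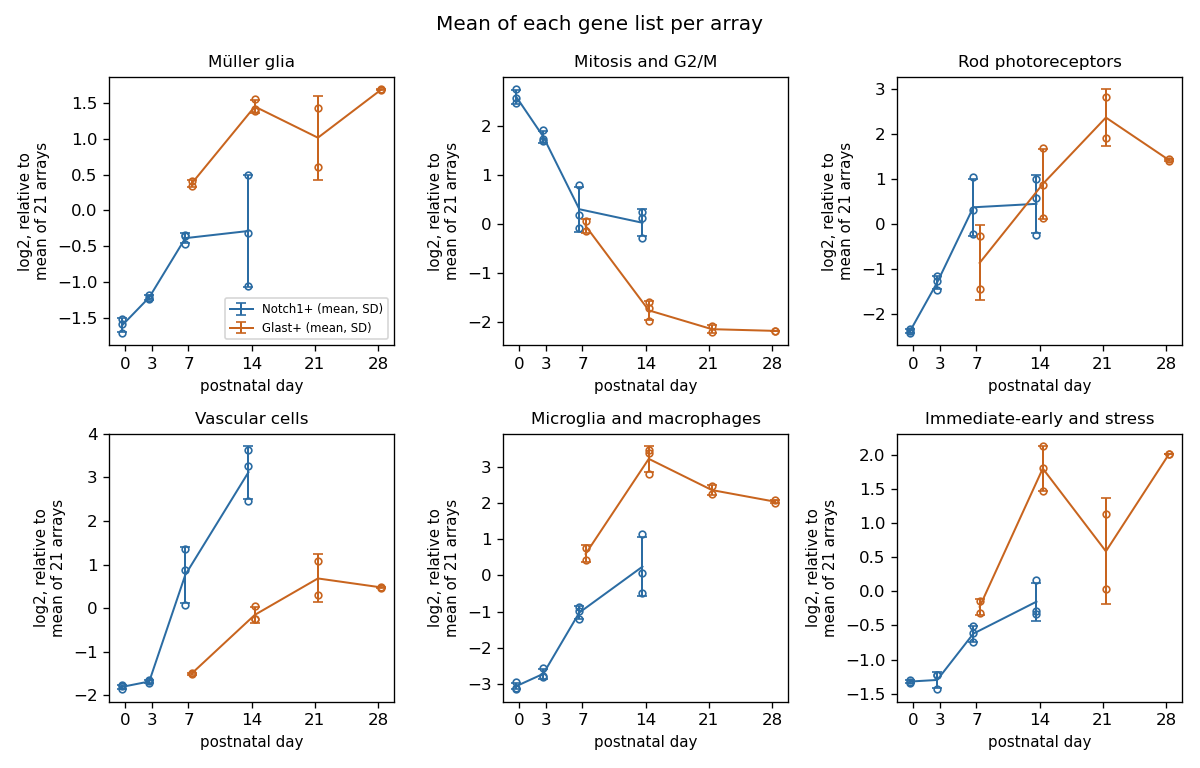
Mean of 6 gene lists in each array relative to the mean of all 21 arrays (y axis, log2) by postnatal day (x axis) and sort (colour). Each point is an array, and lines give the group mean and its SD. The vascular list reaches a group mean of 3.12 in Notch1+ cells at P14 and −0.16 in Glast+ cells of that age, and the microglial list 0.24 and 3.22.

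From P0 to P3 the Notch1+ cells changed little, with some rod genes rising and cell-cycle genes falling. Of 12612 genes, 250 were called, 94 higher and 156 lower. The rod genes Pde6b (3.27, SE 0.53, adjusted p = 0.00256), Prph2 (3.02, SE 0.51, adjusted p = 0.00367) and Sag (2.78, SE 0.58, adjusted p = 0.0166) had the largest rise, and Rlbp1 rose by 2.44 (SE 0.48, adjusted p = 0.0122). The binding protein gene Crhbp (−2.80), Sstr2 (−2.59) and Igfbp5 (−2.49) had the largest fall, with SE 0.28 to 0.44 and adjusted p = 9.34e-05 to 0.00374. No call was made for Notch1 (−0.04), Slc1a3 (0.75) or Glul (0.44), with adjusted p = 0.602 to 1. Ccnd1 was saturated at both ages and Gfap found on 1 of 6 arrays, so neither has a size here. Glycolysis genes (7 of 19 higher, 13 adjusted over the list alone, median 0.75, adjusted p = 3.09e-20) rose and sterol synthesis genes (5 of 19 lower, 8 adjusted over the list alone, median −0.65, adjusted p = 1.43e-12) fell, both also with an estimated correlation (adjusted p = 0.000567 and adjusted p = 0.000195). Mitosis genes were lower in 5 of 33 cases (27 adjusted over the list alone, median −0.88), replication genes in 1 of 29 (14 adjusted over the list alone, median −0.61) and neurogenic factors in 3 of 22 (5 adjusted over the list alone, median −0.32). Rod genes were higher in 6 of 27 cases (9 adjusted over the list alone, median 0.84) and Müller glia genes in 2 of 23 (3 higher and 1 lower adjusted over the list alone, 0.29). Cone (0.23), glial transport (0.34), microglial (0.33) and synaptic vesicle genes (0.32) rose too. For these 9 lists adjusted p = 1.75e-22 to 0.0155, and adjusted p = 0.0702 to 0.706 with an estimated correlation. With fry only mitosis and replication among them were called (adjusted p = 0.223 to 0.628 for the other 7).

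The P3 count changed when a single array was left out, which also lowers the power of the test. It was 95, 146 and 114 without replicate 1, 2 or 3 of P0, and 280, 81 and 94 without replicate 1, 2 or 3 of P3. It was 376 with scan day as a block, 178 within day 2, 149 with median scaling (31 higher and 118 lower) and 602 when only the compared groups were fitted. The Rlbp1 call ended with median scaling (2.47) and without replicate 1 (2.48) or 3 (2.38) of P0 or 2 (2.38) or 3 (2.46) of P3, and the Sag call in the same 5 cases (2.53 to 2.86) and within day 2 (2.86). The calls of neurogenic factors (−0.21) and microglial genes (0.23) ended within day 2, and without replicate 1 of P3 (−0.22 and 0.28).

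From P3 to P7 vascular genes rose in the Notch1+ cells while cell-cycle genes fell further. Of 12612 genes, 1185 were called, 695 higher and 490 lower. Aplnr (5.91), Igfbp7 (5.63) and the endothelial glutamine transporter Slc38a5 (5.33, found on 2 of 3 P3 arrays) had the largest rise, with SE 0.31 to 0.46 and adjusted p = 3.36e-08 to 3.31e-07. Ptf1a (−3.44), the keratin gene Krt73 (−3.22, found on 1 of 3 P7 arrays) and Atoh7 (−3.19) had the largest fall, with SE 0.21 to 0.24 and adjusted p = 8.8e-08 to 2.64e-07. Rlbp1 rose by 2.13 (SE 0.48, adjusted p = 0.00834). Notch1 (−0.41), Slc1a3 (0.88) and Glul (0.06) were not called, with adjusted p = 0.217 to 0.97. Ccnd1 was saturated at both ages and Gfap found on no array, so neither has a size here. Mitosis (28 of 33 lower, 31 adjusted over the list alone, median −1.62), replication (−1.12) and sterol synthesis genes (−0.46) fell. Vascular (13 of 21 higher, 14 adjusted over the list alone, 2.73), matrix (1.13) and lens genes (0.63) rose. These 6 calls, with adjusted p = 9.08e-32 to 0.00127, held with an estimated correlation (adjusted p = 0.0231 to 0.0488).

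Neuronal and glial lists rose in the same interval. Rod genes were higher in 15 of 27 cases (16 adjusted over the list alone, median 1.82), microglial genes in 13 of 20 (15 adjusted over the list alone, 1.81) and Müller glia genes in 7 of 23 (8 adjusted over the list alone, 0.72). Bipolar (median 1.05), glial transport (0.48), interferon (0.60), synaptic vesicle (0.67), immediate-early and stress (0.51), astrocyte (0.82), erythroid (0.54), cone (0.63), gliosis (0.17) and glycolysis genes (0.24) also rose. Neurogenic factors (7 of 22 lower, 8 adjusted over the list alone, −0.36) and chromatin genes (−0.19) fell. For these 15 lists adjusted p = 5e-14 to 0.0405, and adjusted p = 0.0841 to 0.432 with an estimated correlation. The glycolysis call ended within day 2 (0.24, adjusted p = 0.297), with the authors' values (0.07), and without replicate 1 of P3 (0.31) or 1 (0.24) or 2 (0.18) of P7. The cone call ended with fry (adjusted p = 0.187), within day 2 (0.61) and without replicate 1 of P3 (0.60) or of P7 (0.32), and the gliosis call with median scaling (0.21) and without replicate 2 of P3 (0.15). The count of genes was 1374 with scan day as a block, 472 within day 2, 588 higher and 258 lower with median scaling, 774 and 778 without replicate 1 or 3 of P3, and 634 and 651 without replicate 1 or 2 of P7.

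Between P7 and P14 vascular and interferon genes rose in the Notch1+ cells and progenitor and neurogenic genes fell, with replicate 3 of P14 showing the least of it. Of 12612 genes, 3552 were called, 1808 higher and 1744 lower. The matrix protein gene Mgp (4.65), the pericyte gene Higd1b (4.25) and Ly6a (4.09), present on endothelial cells, had the largest rise, with SE 0.36 to 0.47 and adjusted p = 2.96e-06 to 2.21e-05. The radial glial fatty-acid-binding protein gene Fabp7 (−4.62), the ephrin receptor gene Epha8 (−4.06) and Plppr3 (−3.95) had the largest fall, with SE 0.56 to 0.86 and adjusted p = 8.88e-05 to 0.000749. Notch1 fell by 0.54 (SE 0.19, adjusted p = 0.0397), Glul rose by 1.14 (SE 0.37, adjusted p = 0.0268) and Ccnd1, saturated at P7, was at least 1.85-fold lower (adjusted p = 0.0139). No call was made for Slc1a3 (−1.03, adjusted p = 0.0734), Rlbp1 (−0.91, adjusted p = 0.18) or Gfap, found on no array. Without replicate 3 of P14, Slc1a3 (−1.67) and Rlbp1 (−1.54) were called. The Notch1 call ended with the 3 other scalings (−0.31 to −0.62), within day 2 (−0.50), and without any array but replicate 3 of P14 (−0.45 to −0.59). The Glul call ended with median scaling (0.95) and without replicate 2 of P7 (0.94) or 1 (0.86) or 3 (1.06) of P14, and that of Ccnd1 with the 3 other scalings, within day 2 and without replicate 2 of P7 or 1 of P14.

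Vascular genes were higher at P14 than at P7 in 18 of 21 cases (18 adjusted over the list alone, median 2.54) and interferon genes in 15 of 19 (17 adjusted over the list alone, 1.72). Microglial (1.42), matrix (1.14) and gliosis genes (0.49) rose too, microglial ones most in P14 replicate 3 (1.13, against 0.07 and −0.47). Neurogenic factors were lower in 16 of 22 cases and higher in 1 (17 and 1 adjusted over the list alone, −1.56) and progenitor genes in 13 of 19 with 1 higher (15 and 1 adjusted over the list alone, −1.31). Synaptic vesicle (−0.84) and chromatin genes (−0.34) fell too. In replicate 3 of P14 the progenitor mean (−0.01, against −1.30 and −1.57) lay within the P7 arrays (−0.03 to 0.28), and the neurogenic (0.09, against −1.41 and −1.37) and interferon means (0.12, against 1.35 and 1.44) were nearer to P7 than in the other 2. Without it the progenitor and interferon medians were −1.59 and 2.25. For these 9 lists adjusted p = 3.97e-13 to 0.0292, and adjusted p = 0.385 to 0.568 with an estimated correlation. The calls of gliosis (0.28) and chromatin genes (−0.36) ended without replicate 3 of P14, and that of synaptic vesicle genes within day 2 (−0.62). The gene count was 4142 with scan day as a block, 2308 within day 2, 1250 when only the compared groups were fitted, and 2264 higher and 1345 lower with cyclic loess.

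The comparison of Glast+ cells at P28 and P7 asks how Müller glia differ from their precursors. The lists of reactive gliosis, immediate-early and rod genes rose, and those of mitosis and neurogenic factors fell. Of 12612 genes, 4691 were called, 2282 higher and 2409 lower at P28, and 2997 with the P28 arrays averaged to 1 replicate. The water channel gene Aqp4 rose by 6.49 (13.53 ± 0.01 at P28, 7.04 ± 0.33 at P7, SD, n = 2 arrays each, adjusted p = 1.07e-08), but its 3 probes ranged from −0.15 to 6.49. Guca1b, a guanylate cyclase activator of photoreceptors (7.23, SE 0.81, adjusted p = 5.49e-06), Mgp (6.45), the lipid transporter gene Abca8a (6.4), the rod exchanger gene Slc24a1 (5.98) and the procollagen enhancer gene Pcolce2 (5.93) complete the 6 largest rises, the last 4 with SE 0.38 to 0.93 and adjusted p = 1.07e-08 to 0.00012. Mgp was found on 1 of 2 and Pcolce2 on neither P7 array, and Pcolce2 was at least 61-fold higher (2.11 on the log2 scale by its other probe). Fabp7, found on no P28 array, was at least 63.7-fold lower (adjusted p = 0.000346). The next largest falls were those of Mycl (−5.33), the acetylcholine receptor gene Chrna4 (−4.84), the Notch effector Heyl (−4.58), the Wnt modulator Sfrp2 (−4.50) and the cytokinesis gene Prc1 (−4.48), with SE 0.41 to 0.83 and adjusted p = 7.62e-07 to 0.000277.

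Among the genes fixed beforehand, Notch1 fell by 1.43 (SE 0.23, adjusted p = 0.000165) and Ccnd1 by 1.31 (SE 0.31, adjusted p = 0.00334) in Glast+ cells. Glul rose by 2 (SE 0.45, adjusted p = 0.00233). Slc1a3 (−0.04, adjusted p = 0.962), Rlbp1 (0.44, adjusted p = 0.597) and Gfap (1.30, adjusted p = 0.115) were not called. The Glul call ended with median scaling (1.35). Müller glia genes were higher in 8 of 23 cases (10 higher and 1 lower adjusted over the list alone, median 0.60), with Clu, saturated at P28, at least 18.1-fold higher. Glial transport genes were higher in 9 of 19 cases (10 adjusted over the list alone, 1.29). Reactive gliosis genes rose in 15 of 22 cases and fell in 1 (16 and 2 adjusted over the list alone, 1.98), with the serpin gene Serpina3n at 5.62, the complement gene C4b at 3.54 (0.22 by another probe) and Nes at −3.1 (0.04 by its other probe). Immediate-early and stress genes were higher in 18 of 24 cases (19 adjusted over the list alone, 2.23), among them Atf3 (3.62) and Junb (3.42). Sterol synthesis genes rose in 10 of 19 cases and fell in 2 (the same adjusted over the list alone, 0.88), but not with median scaling (0.13, adjusted p = 0.055). For these 5 lists adjusted p = 3.07e-09 to 0.00493, and adjusted p = 0.0914 to 0.491 with an estimated correlation.

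Mitosis genes were lower at P28 in 26 of 33 cases (27 adjusted over the list alone, median −2.12), with the cyclin Ccna2 at −3.93, and replication genes in 20 of 29 with 1 higher (21 and 1 adjusted over the list alone, −1.08), with Mcm7 at −2.50. Neurogenic factors were lower in 14 of 22 cases (16 adjusted over the list alone, −1.87), including Sox4 (−3.29) and Sox11 (−1.85), and Notch pathway genes in 10 of 24 with 2 higher (11 and 2 adjusted over the list alone, −0.96), where the repressor Hes1 rose by 2.52 and the glycosyltransferase Mfng fell by 1.94. Chromatin genes were lower in 10 of 28 cases and higher in 1 (11 and 1 adjusted over the list alone, −0.50), with the methylation cofactor Uhrf1 at −3.30. Genes of other cell types rose beside the glial ones: rod genes in 15 of 27 cases (15 adjusted over the list alone, 1.79), vascular genes in 13 of 21 with 1 lower (the same adjusted over the list alone, 1.85), including the tight junction gene Cldn5 (5.05), and microglial genes in 12 of 20 (13 adjusted over the list alone, 1.4), including Tmem119 (5.06). Interferon and MHC class I genes were higher in 16 of 19 cases (16 adjusted over the list alone, 2.29), with H2-K1 at 3.05, and astrocyte (0.82) and erythroid genes (0.70) rose too. For these 11 lists adjusted p = 1.53e-15 to 0.0477, and adjusted p = 0.102 to 0.381 with an estimated correlation. The erythroid call ended with the P28 arrays averaged (adjusted p = 0.0551) and without replicate 2 of P7 (0.81) or of P28 (0.57).

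Between P28 and P7, 3000 and 3125 genes were called without replicate 1 or 2 of P28. Fitting only the compared groups gave 7189 calls, median scaling 867 higher and 3160 lower, and cyclic loess 2055 higher and 1360 lower. Glycolysis genes, uncalled, had a median of −0.03, a mean of 0.07 and a downward test (adjusted p = 0.865).

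From P7 to P14 the microglial and immediate-early genes of the Glast+ cells rose and their mitosis genes fell. Of 12612 genes, 3478 were called, 1773 higher and 1705 lower. Aqp4 (6.15, SE 0.36, adjusted p = 9.86e-09, and −0.24 by another probe), Guca1b (5.52, SE 0.74, adjusted p = 2.92e-05) and Abca8a (5.11, SE 0.35, adjusted p = 3.26e-08) had the largest rise. Heyl (−5.13, found on 2 of 3 P14 arrays), the LIM-domain gene Fhl2 (−4.14) and Fabp7 (−3.72) had the largest fall, with SE 0.31 to 0.96 and adjusted p = 7.38e-08 to 0.00787. Notch1 (−1.10) and Ccnd1 (−1.52) fell with SE 0.21 to 0.28 and adjusted p = 0.000661 to 0.000841, while Glul (1.65) and Gfap (2.01) rose with SE 0.41 to 0.57 and adjusted p = 0.00634 to 0.0148. The other Gfap probe changed by 0.09 only. Slc1a3 (−0.27) and Rlbp1 (0.36) were not called, with adjusted p = 0.734 and adjusted p = 0.689. Microglial genes were higher in 20 of 20 cases (20 adjusted over the list alone, median 2.46), immediate-early and stress genes in 16 of 24 (17 adjusted over the list alone, 2.14) and Müller glia genes in 7 of 23 (7 adjusted over the list alone, 0.42). Interferon (1.38), rod (1.49, and 0.67 without replicate 2 of P7), vascular (1.46), gliosis (1.26), glial transport (0.91), astrocyte (1.26), pigment epithelium (0.30) and matrix genes (0.51) rose too. Mitosis genes were lower in 28 of 33 cases (28 adjusted over the list alone, −1.76). Replication (−1), neurogenic (−1.07), Notch pathway (−0.64) and chromatin genes (−0.47) fell as well. For these 16 lists adjusted p = 6.35e-16 to 0.0246, and adjusted p = 0.0902 to 0.549 with an estimated correlation.

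In the step from P7 to P14 the gene count was 2147 and 2023 without replicate 1 or 2 of Glast+ P7, 1962 higher and 821 lower with cyclic loess, and 1539 higher and 2394 lower with the authors' values. Calls ended for Glul with median scaling (1.29) and without replicate 2 of P7 (1.49), for Gfap without replicate 1 (1.98) or 2 (2.04) of P7, for Fabp7 without replicate 1 of P7 (−3.49), for pigment epithelium genes without replicate 2 of P14 (0.41), and for matrix genes with median scaling (0.36), with the authors' values (0.46) and without replicate 2 of P7 (0.24) or 3 of P14 (0.33).

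From P14 to P21 genes of cones, rods and bipolar cells rose in the Glast+ cells and immediate-early genes fell. Of 12612 genes, 1599 were called, 825 higher and 774 lower. The bipolar G-protein subunit gene Gng13 (4.47, SE 0.42, adjusted p = 1.54e-05), Lrtm1 (4.37, SE 0.49, adjusted p = 5.78e-05) and the cone arrestin gene Arr3 (4.32, SE 0.71, adjusted p = 0.00123) had the largest rise. The protocadherin gene Pcdhgb7 (−4.03), the activity-regulated gene Arc (−3.62) and the immediate-early factor Egr3 (−3.48) had the largest fall, with SE 0.78 to 1.16 and adjusted p = 0.00677 to 0.0308, but the P21 arrays differed by SDs of 5.05, 3.12 and 2.18 and the calls ended without replicate 2 of P21 (−0.46, −1.41 and −1.93). The other Egr3 probe changed by 0.11. The call of Pcdhgb7 ended without any array of P14 as well (−3.86 to −4.13). None of Notch1 (−0.53), Slc1a3 (−0.55), Glul (−0.05), Rlbp1 (−0.28), Ccnd1 (−0.74) and Gfap (−1.01) was called, with adjusted p = 0.0964 to 0.96. Calls appeared for Ccnd1 with median scaling (−1.01) and without replicate 2 of P14 (−0.98), for Gfap without replicate 2 of P14 (−1.85) and for Notch1 without replicate 2 of P21 (−0.79). Cone genes were higher in 11 of 12 cases (11 adjusted over the list alone, median 2.14), rod genes in 7 of 27 (10 adjusted over the list alone, 1.51) and bipolar genes in 8 of 18 (8 adjusted over the list alone, 1.25). Without replicate 2 of P21 the cone median was 1.5 and the bipolar one 0.52, and without replicate 1 the rod median was 0.74, all still called. Synaptic vesicle (1.03), vascular (1.04), glycolysis (0.43), ganglion cell (0.27) and erythroid genes (0.64) rose too. For these 8 lists adjusted p = 4.38e-09 to 0.0205, and adjusted p = 0.285 to 0.441 with an estimated correlation.

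Falling lists from P14 to P21 were led by immediate-early and stress genes (12 of 24 lower, 16 adjusted over the list alone, median −1.24, and −0.53 without replicate 2 of P21) and microglial genes (3 of 20 lower, 7 adjusted over the list alone, −0.80). Progenitor (−0.46), Müller regeneration (−0.59), mitosis (−0.31), matrix (−0.52), replication (−0.37), Notch pathway (−0.36), gliosis (−0.28) and Müller glia genes (−0.28, 1 of 23 lower, also 1 adjusted over the list alone) fell with 1 to 6 members lower in each. For these 10 lists adjusted p = 5.92e-08 to 0.0438, and adjusted p = 0.285 to 0.649 with an estimated correlation. The gene count was 1041 and 851 without replicate 1 of P14 or of P21, 43 when only the compared groups were fitted, 105 higher and 411 lower with median scaling and 751 higher and 458 lower with the authors' values. The Müller glia median was 0.06 and uncalled without replicate 1 of P21, and its call ended with the replicate block (−0.16), with the authors' values (−0.10) and without replicate 1 (−0.18) or 3 (−0.25) of P14. Without replicate 2 of P21 the calls of replication (−0.34), mitosis (−0.31), ganglion cell (0.03), vascular (0.61), erythroid (0.30) and gliosis genes (−0.20) ended, without replicate 1 of P21 those of the Notch pathway (−0.23) and matrix genes (−0.35), and without replicate 3 of P14 those of the Notch pathway (−0.28), gliosis (−0.15) and matrix genes (−0.44). The mitosis call ended with median scaling (−0.27), and those of the Notch pathway (−0.33) and gliosis genes (−0.22) with the replicate block. Fry ended those of Müller glia, mitosis, replication, progenitor, matrix, vascular and ganglion cell genes (adjusted p = 0.05 to 0.352).

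From P21 to P28 the bipolar and cone genes of the Glast+ cells fell and immediate-early, gliosis and sterol synthesis genes rose. Of 12612 genes, 2266 were called, 1008 higher and 1258 lower, and 601 with the P28 arrays averaged. The chemokine gene Cxcl1 (4.37, SE 0.78, adjusted p = 0.00184), the BMP target Id1 (4.33, SE 0.60, adjusted p = 0.000355) and the ephrin receptor gene Ephb1 (4.32, SE 0.99, adjusted p = 0.00809) had the largest rise. The GABA receptor gene Gabrr1 (−3.96), the bipolar cell factor Isl1 (−3.87) and Pcp4 (−3.79) had the largest fall, with SE 0.62 to 0.70 and adjusted p = 0.0011 to 0.00186. Ccnd1 rose by 0.95 (SE 0.31, adjusted p = 0.0433). Notch1 (0.19), Slc1a3 (0.78), Glul (0.41), Rlbp1 (0.36) and Gfap (0.30) were not called, with adjusted p = 0.308 to 0.792. Sterol synthesis genes were higher in 11 of 19 cases and lower in 2 (12 and 2 adjusted over the list alone, median 0.88, adjusted p = 7.68e-05, adjusted p = 0.0293 with an estimated correlation). Immediate-early and stress genes were higher in 11 of 24 cases (15 adjusted over the list alone, 1.36), gliosis genes in 9 of 22 (11 adjusted over the list alone, 1.10) and Müller glia genes in 3 of 23 (3 adjusted over the list alone, 0.41). Müller regeneration factors (0.81) and progenitor genes (0.34) rose too. Bipolar genes were lower in 12 of 18 cases (14 adjusted over the list alone, −2.32), cone genes in 8 of 12 (10 adjusted over the list alone, −2.20) and rod genes in 4 of 27 (4 adjusted over the list alone, −0.82). Synaptic vesicle (−0.94) and glycolysis genes (−0.29) fell too. For these 10 lists adjusted p = 3.89e-09 to 0.0269, and adjusted p = 0.0857 to 0.665 with an estimated correlation.

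The count between P28 and P21 was 663 and 607 without replicate 1 or 2 of P28, 932 without replicate 1 of P21, 252 with median scaling, 1291 with cyclic loess and 771 when only the compared groups were fitted. Ephb1 was no longer called with median scaling (4.12), with P28 averaged (adjusted p = 0.0619), or without replicate 1 of P21 (4.17) or 1 (4.25) or 2 (4.38) of P28, and Ccnd1 with median scaling (0.87), with the authors' values (0.97), with P28 averaged (adjusted p = 0.17) or without any of the 4 arrays (0.84 to 1.06). Without replicate 1 of P21 the calls of Müller glia (0.00) and rod genes (−0.35) ended, and without replicate 2 that of glycolysis genes (−0.38). Fry ended those of Müller glia, rod and progenitor genes (adjusted p = 0.0551 to 0.226). Without replicate 2 the immediate-early and gliosis medians, still called, were 0.64 and 0.64, and the bipolar and cone medians −1.59 and −1.51.

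The comparison of the sorts at P7 asks how Glast+ cells differ from Notch1+ cells of the same age. Microglial genes were higher and vascular genes lower in Glast+ cells. Of 12612 genes, 1553 were called, 856 higher and 697 lower in Glast+ cells (2 against 3 arrays). The genes of the antibody targets were not called, which for Slc1a3, near the top of the scale, does not show equal levels: Notch1 was at 15.07 ± 0.11 in Glast+ and 14.71 ± 0.13 in Notch1+ cells (SD, adjusted p = 0.296) and Slc1a3 at 15.89 ± 0.16 and 15.61 ± 0.11 (SD, adjusted p = 0.784). With the authors' values both were called higher in Glast+ cells (0.86 and 1.47). Glul (0.61, adjusted p = 0.391), Rlbp1 (0.55, adjusted p = 0.599), Gfap, found on 2 Glast+ and 0 of 3 Notch1+ arrays (adjusted p = 0.406), and Ccnd1, saturated in Notch1+ cells (adjusted p = 0.784), were not called. Ly6h (3.95), Fhl2 (3.84), the chemokine gene Cxcl2 (3.80), the repressor Bcl6 (3.66), Cited4 (3.42) and Sertad1 (3.05) were highest in Glast+ over Notch1+ cells, with SE 0.19 to 0.54 and adjusted p = 3.84e-09 to 0.00143. Cxcl2 was found on no Notch1+ array and was at least 13.8-fold higher. Ly6h, found on 2 of 3 Notch1+ arrays, differed by −0.05 with the authors' values and by −0.38 by another probe. Aplnr (−6.85), Cldn5 (−5.84), Igfbp7 (−5.71), Cd93 (−5.56), Icam2 (−5.26) and Robo4 (−5.17), all known from endothelial cells, were lowest, with SE 0.28 to 0.51 and adjusted p = 3.55e-09 to 8.56e-06. Aplnr and Robo4 were found on 1 of 2 Glast+ arrays, and the other Robo4 probe differed by −0.31.

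Microglial genes were higher in Glast+ cells at P7 in 12 of 20 cases (17 adjusted over the list alone, median 1.61), with the fractalkine receptor gene Cx3cr1 at 2.80 (SE 0.43, adjusted p = 0.000564) and Tmem119 at 1.83. Vascular genes were lower in 11 of 21 (11 adjusted over the list alone, −1.96), with Ramp2, an adrenomedullin receptor component, at −5.12 and Cdh5 at −3.80. Müller glia genes were higher in 7 of 23 cases (9 higher and 1 lower adjusted over the list alone, 0.61), with Timp3 at 2.60 (SE 0.23, adjusted p = 2.94e-06). Gliosis genes were higher in 8 of 22 with 1 lower (9 and 1 adjusted over the list alone, 0.74), with Stat3 at 2.33 and Socs3, its feedback inhibitor, at 2.04. Rod genes were lower in 4 of 27 cases (9 adjusted over the list alone, −1.45, and −0.59 without replicate 2 of Glast+ P7) and neurogenic factors in 4 of 22 (5 adjusted over the list alone, −0.85). Synaptic vesicle (−0.60), cone (−0.94), ganglion cell (−0.20) and erythroid genes (−0.62) were lower too. Mitosis genes, with the kinase Plk1 at −1.24, and replication genes, with Tk1 at −1.58, were lower in 4 members each (4 adjusted over the list alone, medians −0.34 and −0.30). Regeneration factors (0.50), astrocyte (0.83) and lens genes (0.42) were higher. For these 15 lists adjusted p = 4.57e-12 to 0.0439, and adjusted p = 0.236 to 0.64 with an estimated correlation.

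The Notch pathway list was not called at P7 (median 0.09, adjusted p = 0.296, though adjusted p = 0.00748 with fry), with 6 of 24 members higher and 2 lower (6 and 4 adjusted over the list alone). Its higher members were led by the effectors Hey2 (2.84, SE 0.29, adjusted p = 1.56e-05) and Hey1 (3.02, SE 0.37, adjusted p = 7.68e-05) and the feedback regulator Nrarp (1.92, SE 0.23, adjusted p = 7.68e-05). The CDK inhibitor Cdkn1b (p27) was 2.91 higher in Glast+ cells (SE 0.30, adjusted p = 1.37e-05), and 0.77 by its other probe. Matrix genes, uncalled, had a median of 0.25, a mean of −0.28 and a downward test (adjusted p = 0.514), and glial transport genes a median of 0.08, a mean of −0.14 and a downward test (adjusted p = 0.725).

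The P7 count was 705 and 551 without replicate 1 or 2 of Glast+ P7, 1000 without replicate 1 of Notch1+ P7, 312 higher and 929 lower with median scaling, and 1637 higher and 532 lower with the authors' values. List calls that ended without a single array were those of mitosis (−0.08 and −0.23) and replication genes (−0.19 and −0.21) without replicate 3 of Notch1+ P7 or 1 of Glast+ P7, and of synaptic vesicle genes (−0.34) and regeneration factors (0.67) without replicate 2 of Glast+ P7. The same held for cone (−0.52 and −0.21) and ganglion cell genes (−0.12 and −0.19) without replicate 1 of Notch1+ or 2 of Glast+ P7, and for astrocyte genes (0.87 and 0.80) without replicate 3 of Notch1+ or 2 of Glast+ P7. It held for erythroid genes (−0.33 to −0.59) without replicate 1 or 2 of Notch1+ or 2 of Glast+ P7, and for lens genes (0.36 to 0.54) without any array but replicate 2 of Notch1+ P7. Median scaling ended the ganglion cell (−0.41) and erythroid (−0.70) calls and the authors' values those of astrocyte (0.97), lens (0.63) and regeneration genes (0.81). Fry ended 9 of the 15, those of Müller glia, neurogenic, replication, mitosis, rod, cone, ganglion cell, erythroid and synaptic vesicle genes (adjusted p = 0.0538 to 0.249).

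At P14 the sorts differed more widely. Glast+ cells had higher glial, microglial and immediate-early genes and lower vascular and cell-cycle genes than Notch1+ cells. Of 12612 genes, 4875 were called, 2539 higher and 2336 lower in Glast+ cells. Arc (6.35), the cytokine gene Il1b (5.70), Rgs1 (5.22), the factor Cebpb (5.10), Cxcl2 (4.99) and Tmem119 (4.93) were highest, with SE 0.24 to 0.70 and adjusted p = 4.2e-10 to 1.8e-06, and Il1b was found on 2 of 3 Notch1+ arrays. Another Rgs1 probe differed by 0.86. The endothelial genes Pcdh12 (−6.74), Ramp2 (−6.16), Vwf (−5.96) and Adgrl4 (−5.51), Prnd (−6.13) and Higd1b (−5.74) were lowest, with SE 0.33 to 0.48 and adjusted p = 1.33e-09 to 6.18e-08, but the other Pcdh12 probe differed by −0.81 only. Rlbp1 was 1.82 higher in Glast+ cells (15.04 ± 0.29 against 13.22 ± 1.43, SD, n = 3 each, adjusted p = 0.00594), Glul 1.11 higher (SE 0.37, adjusted p = 0.0231) and Gfap, found on no Notch1+ array, at least 6.09-fold higher (adjusted p = 0.000592), though its other probe differed by 0.32 on the log2 scale only. Ccnd1 was lower in Glast+ cells (−0.80, SE 0.25, adjusted p = 0.018). Notch1 (−0.19) and Slc1a3 (1.04) were not called, with adjusted p = 0.0553 to 0.468.

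Müller glia genes were higher in Glast+ cells at P14 in 19 of 23 cases (20 higher and 1 lower adjusted over the list alone, median 1.51), among them Aqp4 (4.45, SE 0.32, adjusted p = 1.78e-08, and 0.20 by another probe), Abca8a (3.66) and the hyaluronan receptor gene Cd44 (3.22, and 0.17 by another probe). Microglial genes were higher in 20 of 20 (20 adjusted over the list alone, 3.13), with the myeloid factor Spi1 at 3.81. Immediate-early and stress genes were higher in 18 of 24 (18 adjusted over the list alone, 1.84), with Atf3 at 4.01, and gliosis genes in 14 of 22 with 2 lower (15 and 2 adjusted over the list alone, 1.75), with the chemokine gene Cxcl10 at 4.20. Regeneration factors were higher in 12 of 18 (12 higher and 2 lower adjusted over the list alone, 1.24), with Sox2 at 3.47 and the growth factor receptor gene Egfr at 2.98 (0.33 by its other probe). Astrocyte (2.41) and pigment epithelium genes (0.98) were higher too. Vascular genes were lower in 17 of 21 (17 adjusted over the list alone, −3.92), mitosis genes in 28 of 33 (30 adjusted over the list alone, −1.88), and replication (−1.08) and erythroid genes (−1.26) too. For these 11 lists adjusted p = 1.16e-13 to 0.0116, and adjusted p = 0.17 to 0.278 with an estimated correlation. Not called were rod genes (median 0.29, adjusted p = 0.347), though the transducin gene Gnat1 was 2.19 higher, and progenitor genes (1.45, adjusted p = 0.097), of which 12 of 19 were higher, such as Hes1 (1.72), and 4 lower, such as Nes (−3.37, and −0.21 by its other probe), as many as adjusted over the list alone.

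The P14 count was 3126 when only the compared groups were fitted, and median scaling gave 1493 higher and 2868 lower. Calls ended for Rlbp1 with median scaling (1.4), for Glul with median scaling (0.65) and without replicate 2 of Notch1+ (0.74) or 3 of Glast+ P14 (1.01), for Ccnd1 without replicate 3 of Notch1+ (−0.63) or 1 (−0.76) or 2 (−0.56) of Glast+ P14, and for erythroid genes with median scaling (−1.36) and the authors' values (−1.20). Calls appeared for Slc1a3 with cyclic loess (1.52), the authors' values (1.35) and without replicate 3 of Notch1+ P14 (1.68), and for Notch1 with median scaling (−0.73).

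**Figure D3:**
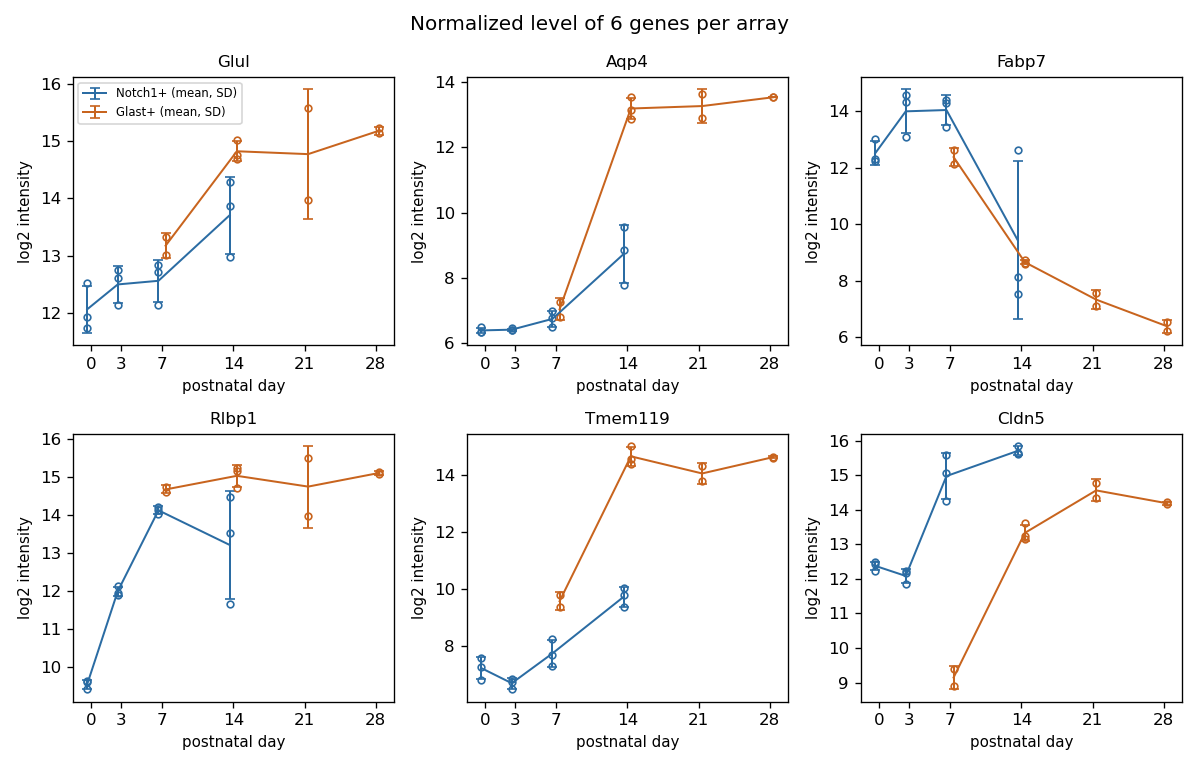
Log2 normalized intensity of Glul, Aqp4, Fabp7, Rlbp1, Tmem119 and Cldn5 (y axis) by postnatal day (x axis) and sort (colour), each for the gene's brightest probe. Each point is an array, and lines give the group mean and its SD. Aqp4 lies at 7.04 in Glast+ cells at P7 and at 13.19 at P14, and Cldn5 at 9.14 and 13.33, while Cldn5 reaches 15.71 in Notch1+ cells at P14.

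The change from P7 to P14 was then set against itself between the sorts, which cancels any constant offset between scan days. Mitosis genes fell more, and microglial and immediate-early genes rose more, in Glast+ than in Notch1+ cells. The difference was called for 1921 of 12612 genes, 1024 higher and 897 lower in Glast+ cells. The condition that arrays do not overlap could not be applied to this contrast. The stress gene Gadd45g had the largest positive difference (3.25 in Glast+ cells, −3.08 in Notch1+ cells, difference 6.33, SE 1.11, adjusted p = 0.00122), followed by Arc (4.68, SE 1.05, adjusted p = 0.0066) and the immediate-early gene Ier2 (4.52, SE 0.67, adjusted p = 0.000355). The largest negative differences were those of Heyl (−5.13 in Glast+ cells and 0.15 in Notch1+ cells, difference −5.28, SE 0.64, adjusted p = 6.94e-05), Fhl2 (−5.03, SE 0.41, adjusted p = 3.24e-06) and Nes (−4.55, SE 0.39, adjusted p = 4.18e-06, and −0.52 by its other probe). Notch1 (−0.56), Slc1a3 (0.76), Glul (0.50) and Rlbp1 (1.27) were not called, with adjusted p = 0.21 to 0.622. Ccnd1, saturated in Notch1+ cells at P7, and Gfap, found on no Notch1+ array at either age, have no size here. Mitosis genes differed downward in 19 of 33 cases (24 adjusted over the list alone, median −1.51) and vascular genes in 6 of 21 with 1 upward (8 and 1 adjusted over the list alone, −0.99). Replication (−0.93) and Notch pathway genes (−0.52) were called downward too. Upward differences were found for 11 of 24 immediate-early and stress genes (14 adjusted over the list alone, 1.69), 6 of 20 microglial genes (10 adjusted over the list alone, 1.42) and 3 of 23 Müller glia genes (5 upward and 1 downward adjusted over the list alone, 0.81). Rod (1.88, and 1.03 without replicate 2 of Glast+ P7), synaptic vesicle (1.09), pigment epithelium (0.75), glial transport (0.76), astrocyte (1.53), gliosis (0.94) and regeneration genes (0.81) were called upward too. For these 14 lists adjusted p = 8.26e-13 to 0.0474, and adjusted p = 0.184 to 0.546 with an estimated correlation.

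The count of differences was 3028 without replicate 3 of Notch1+ P14, 1165 and 983 without replicate 1 or 2 of Glast+ P7, 947 when only the 4 groups were fitted, 337 higher and 447 lower with median scaling, and 736 higher and 1243 lower with the authors' values. Without replicate 3 of Notch1+ P14, Slc1a3 (1.4) and Rlbp1 (1.90) were called, and Notch1 was with the authors' values (−1.19). Fry ended the calls of vascular, Müller glia, rod and regeneration genes (adjusted p = 0.0675 to 0.183). List calls also ended for vascular genes without replicate 3 of Notch1+ P7 (−0.56), for the Notch pathway without replicate 3 of Notch1+ P14 (−0.55), for glial transport genes without replicate 2 of Notch1+ (0.59) or 3 of Glast+ P14 (0.67). The gliosis call ended with median scaling (0.72) and without replicate 2 of Notch1+ P7 (0.82), 3 of Notch1+ P14 (1.13), 2 of Glast+ P7 (0.76) or 3 of Glast+ P14 (0.74), and that of regeneration factors with median scaling (0.67), the replicate block (0.84) and without replicate 2 of Notch1+ P7 (0.75), 1 (0.68) or 2 (0.54) of Notch1+ P14, 1 of Glast+ P7 (0.80) or 3 of Glast+ P14 (1.07).

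The widest comparison sets Glast+ P28 against Notch1+ P0, where sort, age and scan day differ together. Glial and microglial genes were higher and cell-cycle and neurogenic genes lower in Glast+ P28 cells. Of 12612 genes, 6672 were called, 3300 higher and 3372 lower, and 5160 with the P28 arrays averaged. The small heat shock protein gene Cryab (8.90, SE 0.50, adjusted p = 3.45e-10, found on 2 of 3 P0 arrays), Abca8a (found on no P0 array and at least 389-fold higher, adjusted p = 1.67e-11) and the chemokine gene Ccl4 (8.48, SE 0.45, adjusted p = 2.14e-10, found on 1 of 3 P0 arrays, and 6.22 by its other probe) had the largest rise. Sstr2 (−7.57) and the division genes Cdca3 (−7.34) and Cenpe (−6.79, and −1.62 by its other probe) had the largest fall, with SE 0.31 to 0.50 and adjusted p = 6.52e-11 to 3.59e-09. Rlbp1 (5.55), Glul (3.11), Slc1a3 (1.87) and Gfap (2.19) were higher, with SE 0.41 to 0.57 and adjusted p = 2.18e-07 to 0.00399, and Gfap was found on 1 of 3 P0 arrays. The other Gfap probe differed by 0.36 only. Notch1 was lower (−1.52, SE 0.21, adjusted p = 1.23e-05), and Ccnd1 was at least 2.45-fold lower (adjusted p = 0.000973, and −3.73 as log2 by another probe). Müller glia genes were higher in 20 of 23 cases (21 adjusted over the list alone, median 2.47), microglial genes in 20 of 20 (20 adjusted over the list alone, 5.85), rod genes in 21 of 27 (21 adjusted over the list alone, 3.26) and immediate-early and stress genes in 22 of 24 (23 adjusted over the list alone, 3.22). Mitosis genes were lower in 32 of 33 cases (32 adjusted over the list alone, −4.86), replication genes in 29 of 29 (29 adjusted over the list alone, −3.39) and neurogenic factors in 20 of 22 (20 lower and 1 higher adjusted over the list alone, −3.37). For these 7 lists adjusted p = 1.95e-23 to 3.32e-08, and adjusted p = 0.0688 to 0.247 with an estimated correlation. The gliosis call (20 of 22 higher and 1 lower, the same adjusted over the list alone, 3.32, adjusted p = 1.55e-09) held with an estimated correlation (adjusted p = 0.022). Of the other 21 lists 10 were called, with medians from −0.87 (chromatin) to 2.85 (interferon), adjusted p = 5.38e-08 to 0.0393, and adjusted p = 0.0809 to 0.385 with an estimated correlation. Without replicate 2 of P28 the erythroid call ended (0.65, adjusted p = 0.0548). Median scaling gave 1857 higher and 5141 lower.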

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

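Of the tests below only the chance splits were planned before the results were seen. For 5 comparisons of 3 against 3 arrays, all 10 ways to split the 6 arrays were tested with limma. The real split was the only 1 of 10 with as many genes called in each. It gave 5583 genes for Notch1+ P14 against P0, with 1 in the highest other split. Between P3 and P0 it gave 250 against 0 (1385 and 2021 genes unadjusted), where that other split puts both scan-day-1 arrays on a single side, between P7 and P3 1185 against 0 (2623 and 1449 unadjusted), between P14 and P7 3552 against 1277 (also with both day-1 arrays on a single side), and between the sorts at P14 4875 against 227. With 10 splits no share under 0.05 can arise.

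Vascular genes rose by P14 in Notch1+ cells. Within scan day 2 the list's median shift from P0 to P14 was 5.19, and the lowest value over median scaling and the authors' values was 5.21, so neither scan day nor normalization accounts for it. Of 21 members 19 were higher, none of them in another list, though the list's call did not hold with an estimated correlation (adjusted p = 0.102). Endothelial cells captured through Notch1, which they are known to carry, are a possible source. No test here separates them from glia, for this list or for rises such as those of Jag1, Nid2 and Nes.

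Microglial genes were higher in Glast+ cells at both ages. A constant offset between scan days cannot cause the growth of that difference from P7 to P14 (fry adjusted p = 0.0216 for the list, though adjusted p = 0.424 with an estimated correlation). The difference of 1.61 at P7 cannot be told apart from a scan-day offset, because sort and scan day coincide. At P14 20 of 20 members were higher, none shared with another list, which suggests microglia in the Glast+ sort as a hypothesis.

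Immediate-early and stress genes rose from P21 to P28 in Glast+ cells (median 1.36), a call that did not hold with an estimated correlation (adjusted p = 0.144). The microglial list moved by −0.21 in the same step, so a larger share of microglia does not account for the rise. The lowest shift without either P21 array was 0.64, so a single aberrant array does not account for all of it, though the shift without the other array was 1.90. Of 24 members 3 are in another list. Bipolar (−2.32) and cone genes (−2.20) fell in the same step, and the P21 array lowest in immediate-early genes (0.04) was the highest in bipolar (2.09) and cone genes (3.06), so a change in the share of neurons stays open. Handling of the tissue before the sort could raise the same genes and was not tested.

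The change from P7 to P14 differed between the sorts for 1921 genes. Named ones are Gadd45g (6.33), Arc (4.68), Ier2 (4.52), Heyl (−5.28), Fhl2 (−5.03) and Nes (−4.55, and −0.52 by its other probe). Lists with such a difference were those of Müller glia (0.81), glial transport (0.76), the Notch pathway (−0.52), DNA replication (−0.93), mitosis (−1.51), rods (1.88), microglia (1.42), vessels (−0.99), astrocytes (1.53), pigment epithelium (0.75), gliosis (0.94), immediate-early and stress genes (1.69), Müller regeneration (0.81) and synaptic vesicles (1.09). None of these list calls held with an estimated correlation (adjusted p = 0.184 to 0.546). Some ended with fry or without a single array, as given above.

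Some probes of the classes not used here gave signal too. Of 358 viral-class probes 30 lay above the negative controls on all arrays, as did 3 of 37 transgene-class probes and 81 of 766 probes of a further class. What they bind was not tested.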

How the results depend on the processing

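The settings chosen after results were seen are named above. For any value that moved or turned, the cause was not tested. Counts of genes stayed within 1.5-fold in 12 of 12 comparisons without background correction, without the dim filter, with the negative-control filter, with the mean of probes, with a trended prior, with the authors' values and with a replicate block. A kept total does not mean kept calls, as for the sorts at P7 with the authors' values.

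A 2-fold filter cut the counts to 3396 (Notch1+ P14 against P0), 785 (P7 against P3) and 2020 (P14 against P7), to 2143, 936 and 1429 in the Glast+ steps from P7 to P14, P21 and P28, and to 951 and 2916 between the sorts at P7 and P14. Median scaling gave 149 (Notch1+ P3 against P0), 516 and 252 (Glast+ P21 against P14 and P28 against P21) and 784 (difference between the sorts). Cyclic loess gave 1291 (Glast+ P28 against P21). Fitting only the compared groups gave 602 and 1250 (Notch1+ P3 against P0 and P14 against P7), 7189, 43 and 771 (Glast+ P28 against P7, P21 against P14 and P28 against P21), 3126 (the sorts at P14) and 947 (difference). Scan day as a block gave 376 (Notch1+ P3 against P0), and day 2 alone 472 (P7 against P3) and 2308 (P14 against P7). Averaging P28, which leaves that group no spread, gave 2997 against P7 and 601 against P21.

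Leaving out single arrays gave 4753 to 5850 genes for Notch1+ P14 against P0, 81 to 280 for P3 against P0, 634 to 1524 for P7 against P3 and 2547 to 4256 for P14 against P7. It gave 3000 to 3297 for Glast+ P28 against P7, 2023 to 3035 for P14 against P7, 851 to 1643 for P21 against P14 and 607 to 2516 for P28 against P21. It gave 551 to 1338 for the sorts at P7, 4088 to 5360 at P14, 983 to 3028 for the difference and 5169 to 6382 for Glast+ P28 against Notch1+ P0.

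Of the named values 10, all of Ccnd1 or Gfap, were not repeated. The probe was saturated on all arrays, or found on none, in a group of an uncalled comparison or of the difference, so that there is no sign to test, a rule set after the results were seen. Some small changes turned in sign with the scaling. Slc1a3 turned in Glast+ P28 against P7 (0.74 with loess, 0.10 with the authors' values), P14 against P7 (0.05 with loess) and in the difference (−0.12 with the authors' values). Glul turned in Glast+ P21 against P14 (0.03 with loess, 0.19 with the authors' values) and in Notch1+ P7 against P3 (−0.08). Rlbp1 turned with median scaling in Glast+ P28 against P7 (−0.27) and P14 against P7 (−0.01). Ly6h was −0.05 at P7 with the authors' values, and Notch1 was 0.03 in P3 against P0 within scan day 2.

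Other signs turned when an array was left out. In Notch1+ cells the ranges were −0.09 to 0.03 for Notch1 in P3 against P0, −0.12 to 0.27 for Glul in P7 against P3, −0.04 to 1.14 for Slc1a3 in P14 against P0, and −0.47 to 0.01 for the CDK inhibitor median in P14 against P0, whose test turned at −0.47. In Glast+ cells they were −0.15 to 0.08 for Slc1a3 in P28 against P7. In P21 against P14 they were −0.85 to 0.75 for Glul, −1.23 to 0.12 for Slc1a3, −1.04 to 0.48 for Rlbp1 and −0.60 to 0.06 for the Müller glia median, and in P28 against P21 −0.07 to 0.46 for Notch1, −0.39 to 1.21 for Glul and −0.40 to 1.12 for Rlbp1.

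Of 551 named gene values 474 were kept with median scaling (71 weaker, 3 stronger, 3 turned), 517 with cyclic loess (30 weaker, 1 stronger, 3 turned), 518 with the authors' values (24 weaker, 4 stronger, 5 turned) and 540 with the replicate block (9 weaker, 2 stronger). Scan day as a block, which is balanced over ages and can change only the spread, kept 159 of 159, day 2 alone 149 of 159, averaged P28 arrays 124 of 143 and leaving out arrays 2655 of 2971. Of 179 list calls 170 were kept with median scaling, 172 with the authors' values, 175 with the replicate block, 148 with fry and 11 with an estimated correlation, 58 and 55 of 60 with scan day as a block and within day 2, 44 of 45 with P28 averaged, and 954 of 1023 when an array was left out.

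The median change of all genes moved with scaling. With median scaling it was −0.152 for Notch1+ P14 against P0, −0.116 for P14 against P7, −0.286, −0.144 and −0.11 for Glast+ P28 against P7, P14 against P7 and P21 against P14, −0.132 and −0.164 between the sorts at P7 and P14, and −0.45 for Glast+ P28 against Notch1+ P0. It was 0.103 for the last with cyclic loess. With the authors' values it was 0.255, 0.125 and 0.254 for the sorts at P7, at P14 and for the widest comparison, and −0.124 for the difference, and with the negative-control filter −0.105 for Glast+ P14 against P7. Signal near background limits fold changes of dim genes, and saturated spots limit those of bright ones.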

Other observations

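The values here were picked after the results were seen. C1qa, of the microglial list, lay at 10.57 and 12.11 in Notch1+ cells at P7 and P14 and at 12.78 and 15.54 in Glast+ cells. At either age alone sort and scan day cannot be told apart. Aqp4 by its brightest probe was near 6.4 in Notch1+ cells at P0 and 8.74 at P14, against 13.19 in Glast+ cells of that age.

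The 2 arrays of Glast+ P21 differed most within that sort, with an SD of 0.471 on the log2 scale. Their means were 1.14 and 0.04 for immediate-early and stress, 0.82 and 2.09 for bipolar and 1.61 and 3.06 for cone genes, relative to all arrays.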
